A study of Mus musculus with 24 samples.

How the data were processed

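The deposited table holds 1 value per gene and library, named by mouse gene symbols. Salmon 0.11.3 was used, per the submitters' processing notes, which do not say for which step. The values are estimated counts per gene as deposited by the authors, with no normalization named, and all but 2 cells are whole numbers. How they were summarized to genes and rounded is not given in the sources used here. The notes also name the human build GRCh38, although the samples are mouse and the symbols are mouse symbols, and its role is not given. No position in the results comes from that build, and positions given here are from GENCODE M21 on GRCm38. Per the labels, the mice were C57BL/6N with genotype Atmwt/wt or Atm-/-, T cells were isolated from spleen with a T cell isolation kit, and libraries were made with a 3′ tag kit (Lexogen QuantSeq FWD). How CD4 and CD8 cells were separated is not given in the sources used here.

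Of 34113 genes, 0610010K14Rik and 0610030E20Rik held the letter f in place of a number in 1 library each and were dropped, which left 34111. Of these, 11473 had no count in any library. CD4 and CD8 libraries were fitted apart, 12 libraries in each fit, and comparisons between CD4 and CD8 cells used all 24. The main fit of 24 held no term for the mouse pool, so it left out the pairing of CD4 and CD8 libraries from the same mice. Genes were kept with filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 12808 genes in CD4, 12650 in CD8 and 13232 in all libraries. Counts were scaled with the trimmed mean of M values, with factors from 0.903 to 1.08 in CD4 and 0.972 to 1.04 in CD8 libraries. Each comparison was a contrast of group means in the robust edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, with 8 residual degrees of freedom in the fits of 12 libraries and 16 in the fit of 24. Each library is 1 replicate, a pool of 1 to 3 mice, and n = 3 per group. Standard errors cover the variation among libraries and the counting error that the model holds, and no error of isolation or pooling beyond it.

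The groups, comparisons, 39 gene lists and alternatives were fixed before the data were examined. The lists covered T cell states, pathways, other cell types and sample checks. Each was tested with camera, once with a preset correlation of 0.01 and once with a correlation estimated from the residuals, and the text gives the latter. List members were also adjusted over the list alone. List scores are the mean log2 CPM of the members, with a prior count of 2. Atm was named first in each group, then Cd4, Zbtb7b, Cd8a and Cd8b1. For the 8 comparisons of 2 groups, the genes named were the 10 largest rises and 10 largest falls among genes that passed, had no overlap between libraries and averaged at least 5 CPM in the higher group. Immunoglobulin and T cell receptor segments, predicted genes and genes on lists of other cell types were left out there. For each list up to 4 members that passed, with the smallest p, were named, or up to 3 with the highest expression where none passed. Not every list member that the rule allows is printed.

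The alternatives were DESeq2 size factors in edgeR, upper-quartile normalization, no filter, a stricter filter (30 counts in 3 libraries), DESeq2 1.42.0, limma 3.58.1 voom with sample weights, the share of mice with a B identifier or the B cell score as a covariate, removal of 387 immunoglobulin and 196 other cell type genes, each library left out in turn, all 24 libraries in 1 fit, only the 6 libraries compared, and the replicate number or mouse pool as a block. After the data were seen, a Y-linked score (Ddx3y, Eif2s3y and Uty) and the pan-T score were added as covariates, and for lists each library left out in turn and the Y-linked score. The Y-linked score first held Kdm5d as well, which was left out after it was seen high in 1 library.

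Replicate numbers of CD4 and CD8 libraries from the same mice pair by label, and their residual correlations ran from -0.147 to 0.639 over 12 pairs. Libraries with the same number within a co-receptor come from different mice, with correlations from -0.377 to 0.436 over 24 pairs. In CD4 lymphoma KO against WT all 3 same-number correlations were above 0.1 (0.436, 0.305 and 0.425), where blocking on the number left the count at 0. The code was tested on simulated data of the same design with 100 genes changed by 2-fold and another 100 by 4-fold in each simulation. Each gene had the same spread in all groups there, and libraries were drawn independently. Groups of uneven spread and links between libraries were thus left out, and the numbers recovered may be too high for the real libraries. In the 8 comparisons within a co-receptor edgeR recovered 28 to 53 at 2-fold and 79 to 83 at 4-fold. In the CD4 interaction it recovered 10 and 55, in the CD8 interaction 15 and 67, in the WT and KO differences between CD8 and CD4 responses 28 and 68 and 27 and 65, and in CD8 against CD4 WT controls 49 and 73. Among unchanged genes edgeR called 6 to 12 and DESeq2 19 to 38 in the 8 comparisons within a co-receptor. These were among 116 to 144 and 160 to 183 genes called in all. The share of false calls was above 0.05 in all 8 with DESeq2 and in 5 of them with edgeR. With 1 simulation per comparison, the edgeR shares do not show whether the threshold was exceeded. A count of 0 in an interaction leaves room for many changes of these sizes. An interferon list raised 2-fold was called in all 13 simulations. Genes were drawn independently there, so this does not show the power of the list tests on real genes, which are correlated. R was 4.3.3. Log2 values are given to 2 decimals and other values to 3 significant digits.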

Results

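The series measured polyadenylated RNA of splenic T lymphocytes from mice with an intact Atm gene (wild type, WT) or with both copies disrupted (KO). Atm encodes a kinase that signals from broken DNA. Mice of each genotype had either received B-cell lymphoma cells or no transplant (control), and CD4 and CD8 libraries were made from the same mice. This gave 24 libraries in 8 groups of 3, from 12 pools holding 22 mice in all. Each WT lymphoma library came from 1 mouse, and each other library from 2 or 3 mice. Total counts ran from 6470482 to 10196062 per library, 15263 to 17707 genes had a count, and the 10 most abundant genes of a library took 7.45 to 11.6% of its counts. Fold changes are given on the log2 scale with their standard error after ±. Expression levels are in CPM (counts scaled to a common library total), as mean ± SD of the 3 libraries of a group. The words rose and fell stand for an adjusted p under 0.05 in the edgeR quasi-likelihood test.

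The labels were examined first. Atm itself (GRCm38, chromosome 9, 53439149 to 53536740) stood lower in every KO library than in every WT library of the same co-receptor and condition, where chance separates 3 from 3 libraries in either direction in 10% of comparisons. In CD4 controls Atm was at 82.2 ± 2.59 in KO and 177 ± 21.3 in WT libraries (log2 fold change -1.12 ± 0.38, adjusted p = 0.151), and in CD8 controls at 103.5 ± 12.7 and 204 ± 13.4 (-0.95 ± 0.24, adjusted p = 0.122). With lymphoma it was at 65.5 ± 39.3 and 146 ± 29.5 in CD4 (-1.16 ± 0.38, adjusted p = 0.365) and at 75.1 ± 30.4 and 175.7 ± 17.2 in CD8 libraries (-1.24 ± 0.24, adjusted p = 0.0567). None of these differences passed the adjusted threshold. The allele is not given in the sources used here. Tags from a part of the transcript that the disruption left in place would count as Atm, but where the remaining tags come from was not tested. In KO lymphoma 3 Atm was at 23.99 in CD4 and 40.45 in CD8 libraries. KO lymphoma 1 and 2 had 70.35 and 102.1 in CD4 and 87.67 and 97.3 in CD8 libraries. Y-linked RNA (Ddx3y, Eif2s3y and Uty summed) differed between the groups compared. In CPM it was 68.1, 189 and 125 in the CD4 WT controls, 2.69, 1.25 and 57.7 in the CD4 KO controls, 4.80, 1.88 and 117 in the CD4 WT lymphoma and 0.986, 3.00 and 51.5 in the CD4 KO lymphoma libraries. Genotype and lymphoma comparisons that use the WT controls are thus partly confounded with Y-linked RNA, and so with the sex mix of the pools.

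The co-receptor labels were compared in untreated WT mice. Cd8a was at 509 ± 47.2 in CD8 and 8.52 ± 3.62 in CD4 libraries (5.92 ± 0.64, adjusted p = 8.14e-06), and Cd8b1 at 629 ± 87.1 and 25.7 ± 2.76 (4.62 ± 0.43, adjusted p = 1.18e-06). Cd4 was at 4.33 ± 2.91 in CD8 and 126 ± 8.86 in CD4 libraries (-4.83 ± 0.48, adjusted p = 3.11e-06), and Zbtb7b, the transcription factor that commits thymocytes to the CD4 lineage, at 8.44 ± 5.91 and 97.9 ± 3.12 (-3.51 ± 0.34, adjusted p = 1.43e-06). In all, 246 genes were higher and 214 lower in CD8 than in CD4 WT control libraries, in a fit without a term for the mouse pool. Of the 15 CD8 lineage genes measured, 13 were higher, among them Itgae (5.03 ± 0.39), which encodes an integrin chain, and Nkg7 (2.83 ± 0.27), a protein of cytotoxic granules. Of the 10 CD4 lineage genes, 8 were lower. The same numbers passed adjusted over the list alone, with adjusted p = 0.000564 for both lists with an estimated correlation. Of 17 regulatory T cell genes 11 were lower and 1 higher (13 and 1 adjusted over the list alone, adjusted p = 0.00111 with an estimated correlation), among them Il2ra (-3.15 ± 0.21) and Izumo1r, the folate receptor 4 gene (-1.90 ± 0.15). Of 15 follicular helper genes 8 were lower (9 adjusted over the list alone, adjusted p = 0.00576 with an estimated correlation), with Icos at -0.77 ± 0.16. Of 29 effector and cytotoxic genes 11 were higher and 2 lower (13 and 2 adjusted over the list alone, adjusted p = 0.185 with an estimated correlation), with Eomes at 2.14 ± 0.21 and Klrd1 at 2.50 ± 0.27. Leaving out 1 library gave 281 genes without WT control 1 of either co-receptor, the lowest counts, and up to 377. Without CD4 WT control 2 it was 305. The follicular helper genes were 5 without CD4 WT control 2 or CD8 WT control 1. The lower effector genes were 0 without CD8 WT control 1 and 1 without CD4 WT control 2, CD4 WT control 3 or CD8 WT control 3.

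**Figure D1:**
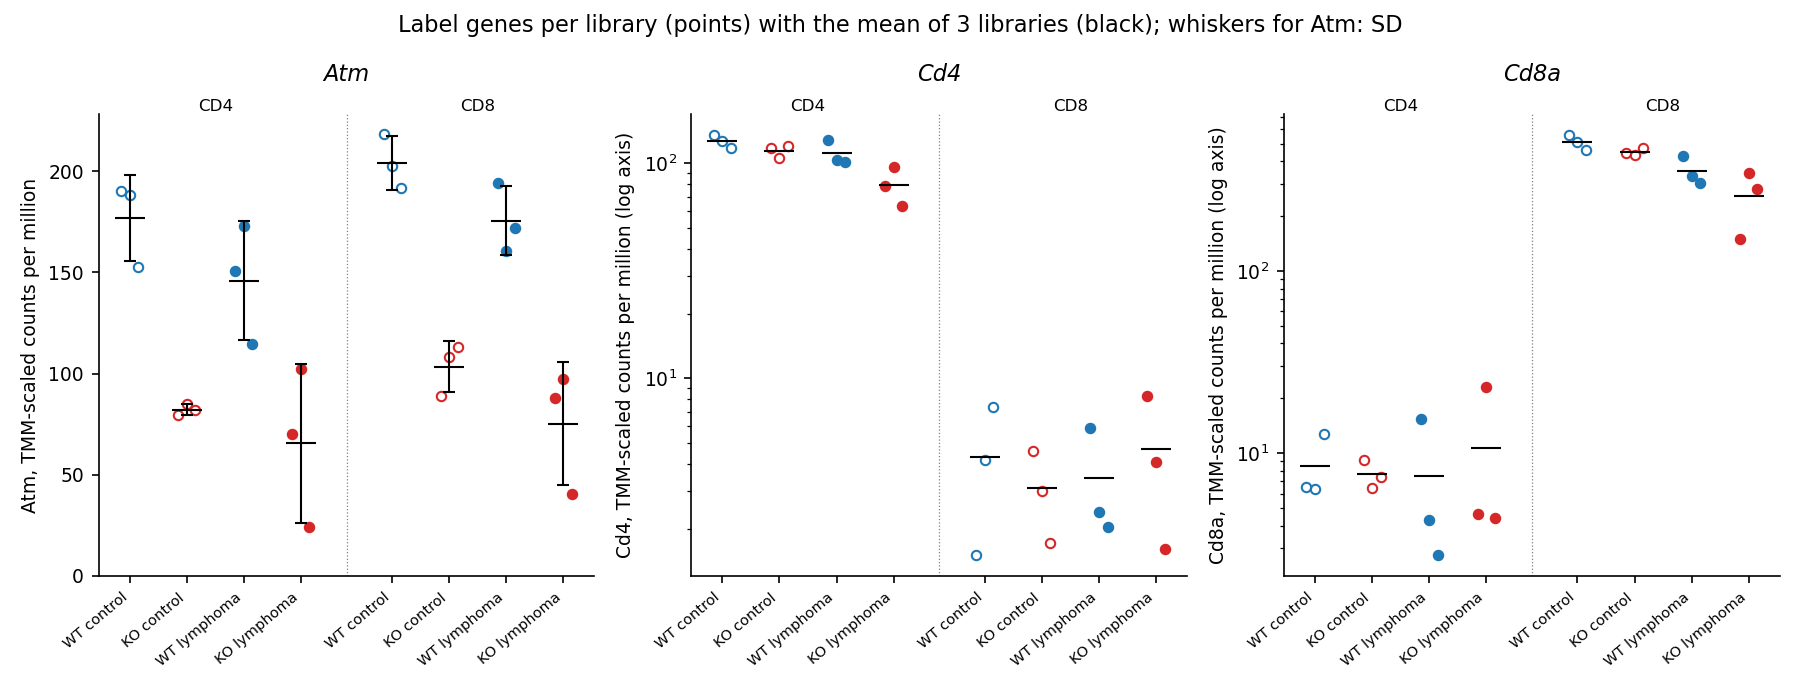
CPM of Atm (linear axis) and of Cd4 and Cd8a (log axes) in each library by group, with open circles for control and filled circles for lymphoma, blue for WT and red for KO; black lines are means of 3 libraries, with the SD as whiskers for Atm. Atm averaged 82.2 in CD4 KO and 177 in CD4 WT controls, and Cd8a 509 in CD8 and 8.52 in CD4 WT controls.

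The first question was how CD4 T cells of WT mice with lymphoma differed from those of WT mice without it. A part of the interferon-stimulated genes rose. Oasl2, a gene of the antiviral oligoadenylate synthetase family, went from 3.57 ± 0.638 to 26.1 ± 7.65 CPM (2.85 ± 0.28, adjusted p = 0.00311), and Cmpk2, a nucleotide kinase induced by interferon, from 5.84 ± 2.61 to 33.2 ± 8.18 (2.48 ± 0.29, adjusted p = 0.00311). Of 52 type I interferon genes measured, 28 rose and 36 did so adjusted over the list alone (median 0.97), with adjusted p = 0.262 with an estimated correlation. Oas1a (2.08 ± 0.23), Oas1g (3.73 ± 0.48) and Lgals3bp (1.42 ± 0.17) were among them. Of 32 interferon gamma response genes 3 rose, the guanosine triphosphatases Irgm1 (0.92 ± 0.18), Gbp5 (0.98 ± 0.19) and Iigp1 (1.39 ± 0.30), and 10 did so adjusted over the list alone (adjusted p = 0.262 with an estimated correlation).

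Other T cell genes also moved in CD4 WT lymphoma libraries. Of 15 follicular helper genes 3 rose and 5 did so adjusted over the list alone (adjusted p = 0.262 with an estimated correlation): the transcription factor Maf (0.94 ± 0.14, 293 ± 20.7 against 153 ± 23.3), the cytokine gene Il21 (2.21 ± 0.40) and Tox2 (1.21 ± 0.23). Ly6c2, a surface protein of memory T cells and monocytes, rose by 2.07 ± 0.23. Ccl4, which encodes a chemokine of activated T cells, rose by 1.88 ± 0.38. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, rose by 2.78 ± 0.44 from a low level (4.74 ± 2.22 against 0.682 ± 0.205), the 1 riser of 35 p53 targets measured (1 adjusted over the list alone, adjusted p = 0.501 with an estimated correlation). The early response genes Ier3 (2.51 ± 0.41) and Gadd45b (1.16 ± 0.20) rose, of 23 measured (3 adjusted over the list alone, adjusted p = 0.282 with an estimated correlation). The glycolysis genes Hk2 (1.76 ± 0.38) and Slc16a3 (1.77 ± 0.39) rose, of 22 measured (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.595 with an estimated correlation). Hsph1 (1.17 ± 0.26) was the 1 riser of 17 heat shock genes, with 12 adjusted over the list alone (adjusted p = 0.262 with an estimated correlation). None of 32 mitosis genes and none of 34 S phase genes passed over all genes tested, where 24 and 22 did adjusted over the list alone, with medians of 1.70 and 1.004 and adjusted p = 0.282 and 0.309 with an estimated correlation. Top2a was at 167 ± 68.4 with lymphoma and 52.4 ± 4.31 without (1.66 ± 0.40, adjusted p = 0.0697).

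Outside the lists of other cell types, the largest rises in CD4 WT lymphoma libraries were in Dach1 (4.26 ± 0.75), Slc18a2 (3.73 ± 0.50), Oas1g, Grb10 (3.68 ± 0.78), Cd34 (3.48 ± 0.72), Adgrg1 (3.47 ± 0.49), Samd14 (3.37 ± 0.57), Muc13 (3.27 ± 0.49), Slc22a3 (3.11 ± 0.59) and Meis1 (3.00 ± 0.48). Cd34 encodes a surface marker of blood progenitors (11.3 ± 7.31 against 0.992 ± 0.105), Meis1 a transcription factor of blood stem cells and Adgrg1 an adhesion receptor (62.4 ± 35.9 against 5.58 ± 0.655). The chemokine receptor gene Cxcr6 fell by 0.96 ± 0.21 (35.2 ± 3.69 against 68.2 ± 11.7), as did Cnga1 (-1.04 ± 0.23) and Zfp512 (-0.73 ± 0.16). Markers of other cell types moved with these groups. Of 13 platelet genes 6 rose and 10 did so adjusted over the list alone (median 1.82, adjusted p = 0.262 with an estimated correlation), with Itga2b at 1.81 ± 0.27 and Pf4 at 1.83 ± 0.35. Of 26 monocyte and macrophage genes Lgals3 (1.76 ± 0.29) and Cybb (1.66 ± 0.33) rose and Cd163 (-1.29 ± 0.29) fell, with 14 higher and 1 lower adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). Of 18 neutrophil genes Mpo rose (4.78 ± 1.05), and 13 were higher and 1 lower adjusted over the list alone (median 2.30, adjusted p = 0.262 with an estimated correlation). Of 26 B cell genes none passed either way (median -0.64, adjusted p = 0.932 with an estimated correlation), nor did any of 20 pan-T genes (median -0.30, adjusted p = 0.543).

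In all, 207 genes rose and 9 fell in CD4 WT lymphoma libraries of 12808 tested (216 together, 1943 at an unadjusted p under 0.05). DESeq2 called 678. The count was 31, 80 and 103 without WT control 1, 2 and 3 and 58 and 51 without WT lymphoma 2 and 3. The interferon genes that passed were 17, 18 and 18 without WT control 1, 2 and 3 and 17 and 16 without WT lymphoma 2 and 3, and the platelet genes 0, 1, 3, 1 and 1 in the same order. The interferon gamma response, glycolysis and heat shock genes numbered 0 without any 1 of these 5 libraries. The follicular helper genes were 0, 1 and 0 without WT control 1, WT control 3 and WT lymphoma 2, and the early response genes 0 without WT control 1 or 2 or WT lymphoma 2 or 3. Higher monocyte genes numbered 0, 1, 4, 0 and 0 without WT control 1 and 3 and WT lymphoma 1, 2 and 3. Neutrophil genes numbered 0, 0, 2, 3, 0 and 0 without WT control 1, 2 and 3 and WT lymphoma 1, 2 and 3. Cdkn1a did not pass without WT control 1 or 2, Ccl4 without WT control 1 or 2 or WT lymphoma 2 or 3, and Cd163 and Cxcr6 did not pass without any 1 library.

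The same question in KO mice had a different outcome in the test. None of the 12808 genes passed in CD4 KO lymphoma against CD4 KO control libraries by edgeR, with 1953 at an unadjusted p under 0.05, 343 called by DESeq2 and 703 by limma voom with sample weights. The interferon genes had a median of 0.67, with 28 of 52 higher adjusted over the list alone and adjusted p = 0.458 with an estimated correlation. The interferon score was 6.13 and 6.39 in KO lymphoma 1 and 2, where the WT lymphoma libraries ran from 6.09 to 6.35, and 5.34 in KO lymphoma 3, where the KO controls ran from 5.29 to 5.46. The interferon-stimulated gene Slfn5 was at 470.4 ± 225 with lymphoma and 260 ± 5.91 without (0.86 ± 0.29, adjusted p = 0.219). The S phase gene Stmn1 was at 395 ± 222 and 162 ± 34.8 (1.30 ± 0.38, adjusted p = 0.182), and 17 of 34 S phase genes were higher adjusted over the list alone (adjusted p = 0.458 with an estimated correlation). None of 32 mitosis genes passed (median 1.11). The cytotoxic granule protease gene Gzma was at 112 ± 41.1 and 292 ± 32.7 (-1.38 ± 0.46, adjusted p = 0.22). Of 29 effector genes 9 were lower adjusted over the list alone (adjusted p = 0.458 with an estimated correlation). Other cell types moved here too: adjusted over the list alone, 23 of 26 B cell genes (median -2.03), 9 of 10 MHC class II genes (median -1.89) and 10 of 15 natural killer cell genes (median -1.26) were lower in the lymphoma libraries, each with adjusted p = 0.458 with an estimated correlation and none over all genes tested. Cd74, the MHC class II chaperone, was at 26.9 ± 10.8 with lymphoma and 107 ± 12.8 without (-1.99 ± 0.61, adjusted p = 0.19). CD4 KO lymphoma 3 had the lowest pan-T score of the CD4 libraries (6.95) and the highest mitosis score (5.47). Without KO lymphoma 2 the count was 501, without KO lymphoma 3 it was 18, and without KO control 1 it was 1.

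Whether the lymphoma response of CD4 cells differed between genotypes was tested as an interaction. No gene passed by edgeR, with 466 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by voom, and 1 gene passed without WT control 2 and 1 without WT control 3. The interferon list had a median difference of -0.47 (KO minus WT, none of 52 passing adjusted over the list alone, adjusted p = 0.261 with an estimated correlation) and the effector list of -0.52 (none of 29, adjusted p = 0.256). Across genes, which are not independent replicates, the WT and KO responses of CD4 cells had a Pearson r of 0.55 and a Spearman rho of 0.533. Of the 216 genes called in WT mice, 211 had the same sign in KO mice.

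The CD8 T cells of the same WT mice were compared next. A part of the interferon-stimulated genes rose here as well. Usp18, a protease that limits interferon signalling, went from 9.71 ± 1.26 to 50.1 ± 5.70 CPM (2.39 ± 0.18, adjusted p = 0.000167), and Ifi27l2a from 68.1 ± 8.27 to 218 ± 36.1 (1.71 ± 0.15, adjusted p = 0.000337). Of 52 type I interferon genes 29 rose and 41 did so adjusted over the list alone (median 1.18, adjusted p = 0.299 with an estimated correlation), among them Oas1a (2.38 ± 0.20), Oas1g (4.67 ± 0.97) and Rtp4 (1.81 ± 0.16). Of 32 interferon gamma response genes 3 rose, among them Iigp1 (1.77 ± 0.31) and Irgm2 (0.95 ± 0.19), and 10 did so adjusted over the list alone (adjusted p = 0.484 with an estimated correlation). Heat shock genes rose, 4 of 17 (13 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation): Bag3 (1.38 ± 0.25), Hsp90ab1 (0.61 ± 0.12), Hspa8 (0.52 ± 0.11) and Ahsa1 (0.56 ± 0.12). Of 22 antioxidant genes Srxn1 (1.53 ± 0.22) and Txn1 (adjusted p = 0.0171) rose, with 10 adjusted over the list alone (adjusted p = 0.299 with an estimated correlation). The S phase genes E2f1 (1.58 ± 0.29) and Cdc45 (1.76 ± 0.38) rose, of 34 (17 adjusted over the list alone, adjusted p = 0.484 with an estimated correlation). None of 32 mitosis genes passed over all genes tested, against 21 adjusted over the list alone (median 1.41, adjusted p = 0.484 with an estimated correlation), and none of 23 early response genes, against 16 (adjusted p = 0.428). Of 35 p53 targets Cdkn1a rose (2.37 ± 0.48) and Ccng1, which encodes cyclin G, fell (-0.55 ± 0.12), the same numbers as adjusted over the list alone (adjusted p = 0.705 with an estimated correlation).

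The largest rises outside the lists of other cell types in CD8 WT lymphoma libraries were in the neutrophil chemoattractant gene Cxcl2 (4.84 ± 1.02, 5.23 ± 2.57 against 0.17 ± 0.181), Oas1g, Ly6i (4.16 ± 0.86), the lectin gene Clec4e (3.90 ± 0.83), Slc22a3 (3.65 ± 0.76), Pira2 (3.05 ± 0.59), the stress cytokine gene Gdf15 (3.04 ± 0.47), Adgrg1 (3.04 ± 0.63), Wfdc17 (2.95 ± 0.59) and Klhl23 (2.91 ± 0.63). Falls were smaller. The tetraspanin gene Tspan32 fell by 0.80 ± 0.14 (58.2 ± 4.28 against 103.2 ± 8.10) and the cold-inducible RNA-binding protein gene Cirbp by 0.74 ± 0.15, and the other 8 named falls, Ifitm10, Qrfp, Polr3a, Lpar6, Amn1, Cln3, Pcmtd2 and Oraov1, ran from -1.09 to -0.68. Of 13 platelet genes 6 rose and 10 did so adjusted over the list alone (median 1.67, adjusted p = 0.299 with an estimated correlation), with Treml1 at 2.17 ± 0.25 and Itga2b at 2.15 ± 0.31. None of 26 monocyte and macrophage genes passed over all genes tested, against 12 higher adjusted over the list alone (median 0.91, adjusted p = 0.567 with an estimated correlation). None of 26 B cell genes (median -0.97, adjusted p = 0.807) and none of 20 pan-T genes (median -0.37, adjusted p = 0.684) passed either way.

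In all, 160 genes rose and 20 fell in CD8 WT lymphoma libraries of 12650 tested (180 together, 2256 at an unadjusted p under 0.05). DESeq2 called 799 and voom 901. The count was 57 and 23 without WT control 1 and 3, 271 without WT lymphoma 1, and 40 and 33 without WT lymphoma 2 and 3. The interferon genes that passed were 13 without WT control 3 and 17 without WT lymphoma 3. The platelet genes that passed were 3, 1, 2 and 2 without WT control 1, WT control 3, WT lymphoma 2 and WT lymphoma 3. The heat shock genes were 1, 0, 1, 0 and 0 without WT control 1, 2 and 3 and WT lymphoma 2 and 3. The S phase genes were 7 without WT lymphoma 1 and 0 without any other single library. The interferon gamma response genes were 0, 1, 0, 1 and 0 without WT control 1, 2 and 3 and WT lymphoma 2 and 3. The antioxidant genes were 1, 4, 0, 1 and 1 in the same order. Cdkn1a passed only where WT control 2 or WT lymphoma 1 was left out, and Ccng1 under no such omission.

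In CD8 cells of KO mice with lymphoma, 22 of 52 interferon-stimulated genes rose and 4 of 20 pan-T genes fell. Rsad2, the antiviral enzyme viperin, went from 61.9 ± 20.9 to 525 ± 474 CPM (3.06 ± 0.59, adjusted p = 0.0414), and Isg20, an interferon-induced exonuclease gene, from 5.28 ± 1.44 to 33.1 ± 16.2 (2.62 ± 0.34, adjusted p = 0.0123). Of the type I interferon genes 33 were higher and 1 lower adjusted over the list alone (median 0.75, adjusted p = 0.461 with an estimated correlation), with Ifi27l2a at 1.30 ± 0.15 and Cmpk2 at 1.66 ± 0.21. Of the pan-T genes 19 were lower adjusted over the list alone (median -0.72, adjusted p = 0.461 with an estimated correlation). The 4 that fell were Cd3e, a chain of the T cell receptor complex (-0.95 ± 0.19, 97.71 ± 29.96 against 187.5 ± 14.1), Thy1 (-1.05 ± 0.23, 129.8 ± 44.5 against 267 ± 24.0), Cd247 (-0.76 ± 0.18) and Cd2 (-0.68 ± 0.14). Of 15 CD8 lineage genes the protease gene Ctsw (-1.08 ± 0.19) and Cd7 (-0.62 ± 0.13) fell, and 10 did so adjusted over the list alone (adjusted p = 0.461 with an estimated correlation). A few cell cycle genes rose: Tpx2 (1.86 ± 0.39) and Ube2c (1.84 ± 0.40) of 32 mitosis genes (29 adjusted over the list alone, adjusted p = 0.461 with an estimated correlation), and Gins2 (1.84 ± 0.38), Cdc45 (1.59 ± 0.36), Rrm1 (0.97 ± 0.22) and Lig1 (adjusted p = 0.0498) of 34 S phase genes (25 adjusted over the list alone, adjusted p = 0.461 with an estimated correlation). The chaperone genes Hspa5 (0.64 ± 0.12) and Calr (0.70 ± 0.16) rose of 22 unfolded protein response genes (8 adjusted over the list alone, adjusted p = 0.461 with an estimated correlation), and the antioxidant genes Prdx2 (1.18 ± 0.26), Txn1 (0.74 ± 0.17) and Srxn1 (0.90 ± 0.21) of 22 measured (13 adjusted over the list alone, adjusted p = 0.461 with an estimated correlation).

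Outside those lists, the largest rises in CD8 KO lymphoma libraries were in Prss34, a mast cell and basophil protease gene (5.03 ± 1.12), Cxcl2 (3.91 ± 0.89), the haptoglobin gene Hp (3.66 ± 0.74, 63.6 ± 30.7 against 4.98 ± 0.55), Clec4e (3.27 ± 0.73), Rsad2, Dnph1 (3.03 ± 0.70), Il1rn (2.89 ± 0.51), Isg20 and the red cell membrane skeleton genes Add2 (2.88 ± 0.63) and Ank1 (2.63 ± 0.57). Falls included Carmil2 (-1.29 ± 0.26), Kifc2, Ppm1j, Pacsin1, Qrfp, Smpd5, Clcf1 and Baiap3, the last 7 between -1.22 and -1.06. None of 17 erythroid genes passed over all genes tested, against 17 higher adjusted over the list alone (median 2.93, adjusted p = 0.535 with an estimated correlation). Of 17 neutrophil genes Mmp8 rose (4.35 ± 0.97), with 14 adjusted over the list alone (median 3.97, adjusted p = 0.461 with an estimated correlation). None of 26 B cell genes passed either way (median 1.25, adjusted p = 0.828). CD8 KO lymphoma 1 stood apart in these markers, with 6.74% of its counts on erythroid list genes, a B cell score of 6.59 and a pan-T score of 6.58. CD8 KO control 1 had 756 genes with a count in no other library, where the other libraries had 41 to 90.

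In all, 176 genes rose and 100 fell in CD8 KO lymphoma libraries (276 together of 12650 tested, 3448 at an unadjusted p under 0.05), so that 63.8% of the called genes were higher, against 53.4% of 204 with upper-quartile normalization. DESeq2 called 1499, voom 481, and no gene passed with the pan-T score as a covariate. Without KO control 1, 2 and 3 the count was 0, 5 and 0, and without KO lymphoma 1, 2 and 3 it was 9, 1861 and 50. The interferon genes that passed were 0, 3, 0 and 5 without KO control 1, 2 and 3 and KO lymphoma 1. Over all omissions of 1 library at most 22 were higher, and up to 3 were lower. The pan-T, mitosis and S phase genes that passed numbered 20 lower, 24 higher and 24 higher without KO lymphoma 2, and 0 without any other single library. Without KO lymphoma 2 the CD8 lineage genes were 12 lower, the antioxidant genes 10, the neutrophil genes 9 and the unfolded protein response genes 7 higher. These numbers were 0 without any other single library, except 1 CD8 lineage gene without KO lymphoma 1 and 1 unfolded protein response gene without KO lymphoma 3.

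The interaction in CD8 cells called no gene by edgeR, with 442 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by voom, and 1 gene passed without WT control 2. The interferon list had a median difference of -0.33 (KO minus WT), with 3 of 52 lower adjusted over the list alone and adjusted p = 0.781 with an estimated correlation. The heat shock list had 2 of 17 lower adjusted over the list alone (median -0.51, adjusted p = 0.665 with an estimated correlation). Across genes, the WT and KO responses of CD8 cells had a Pearson r of 0.629 and a Spearman rho of 0.626. Both genotypes shared 62 risers, where independent lists of these sizes would share 2.23, and 6 fallers, where they would share 0.16. Of the 180 genes called in WT mice 179 had the same sign in KO mice.

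The next comparison asked how T cells of untreated KO mice differed from those of untreated WT mice. In CD4 cells, some genes of effector and memory T cells rose. Tbx21, the transcription factor T-bet of Th1 and effector cells, was at 162 ± 31.5 in KO and 60.4 ± 21.4 in WT libraries (1.42 ± 0.23, adjusted p = 0.0242), and Gzmb, a granule protease gene, at 8.21 ± 0.272 and 2.17 ± 0.759 (1.92 ± 0.39, adjusted p = 0.0354). Of 29 effector and cytotoxic genes 7 rose and 26 did so adjusted over the list alone (median 1.14, adjusted p = 0.0997 with an estimated correlation), with Eomes at 1.09 ± 0.22 and Klrg1 at 1.75 ± 0.37. Of 19 memory genes 8 rose and 14 did so adjusted over the list alone (median 0.94, adjusted p = 0.129 with an estimated correlation): S100a6 was higher by 1.41 ± 0.26, Cd44 by 0.99 ± 0.19, Lgals1 by 0.94 ± 0.17 and Anxa2 by 1.44 ± 0.29. Of 13 Th1 genes 4 rose (9 adjusted over the list alone), among them Ifng (1.56 ± 0.33) and Cxcr3 (0.94 ± 0.20). Of 15 follicular helper genes 4 rose (11 adjusted over the list alone), among them Maf (1.39 ± 0.15, 404 ± 28.8 against 153 ± 23.3), Cxcr5 (1.43 ± 0.31) and Pdcd1 (1.37 ± 0.31). Of 17 regulatory T cell genes 4 rose (8 higher and 1 lower adjusted over the list alone), among them Foxp3 (0.67 ± 0.15) and Nrp1 (0.83 ± 0.18). Each of these 3 lists had adjusted p = 0.0997 with an estimated correlation.

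Among stress genes in CD4 KO controls, Hsph1 (1.37 ± 0.26), Hspa8 (0.62 ± 0.13) and Stip1 (0.76 ± 0.16) rose of 17 heat shock genes (10 adjusted over the list alone, adjusted p = 0.151 with an estimated correlation). The CD4 WT lymphoma comparison uses the same WT controls. Genes higher in both, such as Hsph1, Maf and Tox2, are thus not independent findings. The heat shock score was 5.78, 6.00 and 6.11 in the CD4 WT controls and 6.52 to 7.18 in the other CD4 libraries. Srxn1 (1.60 ± 0.28), Cat (0.74 ± 0.15), Fth1 (0.61 ± 0.13) and Hmox1 (1.32 ± 0.29) rose of 24 antioxidant genes (8 adjusted over the list alone, adjusted p = 0.0997 with an estimated correlation). Cdkn1a (2.26 ± 0.44) was the 1 riser of 35 p53 targets (1 adjusted over the list alone, adjusted p = 0.284 with an estimated correlation). Of 52 interferon genes 3 rose, Oas1a (1.32 ± 0.23), Oasl1 (1.29 ± 0.25) and Oasl2 (1.25 ± 0.28), and 11 did so adjusted over the list alone (adjusted p = 0.466 with an estimated correlation).

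Further named rises in CD4 KO controls were Slfn14 (5.98 ± 1.34), Ypel4 (5.10 ± 1.08), Itgae (2.46 ± 0.38, 5.70 ± 0.824 against 1.04 ± 0.403), the fatty acid receptor gene Cd36 (2.33 ± 0.54), Optn (2.09 ± 0.32), Slc22a23 (2.07 ± 0.44), Igsf9 (1.96 ± 0.43), Tox2 (1.87 ± 0.23, 58.4 ± 14.8 against 15.9 ± 4.56) and Gpr137b (1.86 ± 0.35). The acidic ribosomal protein gene Rplp1 (GRCm38, chromosome 9, 61913284 to 61914542) fell by 1.37 ± 0.23, at 3457 ± 129.9 in KO and 8851 ± 3252 in WT libraries (adjusted p = 0.0243), and of 85 ribosomal protein genes Rpl22l1 was the other that fell (-0.65 ± 0.14, the same 2 adjusted over the list alone, adjusted p = 0.284 with an estimated correlation). Itm2a (-1.22 ± 0.25), Cirbp (-0.93 ± 0.15, 36.1 ± 5.53 against 68.4 ± 6.28), Trub1 (-0.86 ± 0.15), Tgfbr3 (-0.85 ± 0.19), Pxylp1 (-0.78 ± 0.17) and Ramp1 (-0.73 ± 0.15) also fell.

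Some markers of other cell types rose beside these groups in CD4 KO controls. Of 26 monocyte and macrophage genes 14 rose and 24 did so adjusted over the list alone (median 1.12, adjusted p = 0.0997 with an estimated correlation), with the complement gene C1qa at 1.18 ± 0.21 and the receptor gene Csf1r at 1.23 ± 0.22. Of 15 natural killer cell genes 4 rose and 12 did so adjusted over the list alone (median 1.44, adjusted p = 0.202 with an estimated correlation), with Tyrobp at 1.32 ± 0.29 and Klrb1b at 1.98 ± 0.44. Of 13 platelet genes 5 rose (9 adjusted over the list alone, adjusted p = 0.229 with an estimated correlation), with Pf4 at 1.69 ± 0.35. Ighm (0.89 ± 0.20) was the 1 riser of 26 B cell genes (2 adjusted over the list alone, median 1.48, adjusted p = 0.229 with an estimated correlation). None of 18 erythroid genes passed over all genes tested, against 17 higher adjusted over the list alone (median 2.57, adjusted p = 0.229 with an estimated correlation). Trbc1, a T cell receptor constant segment, fell by 1.18 ± 0.23, the 1 of 20 pan-T genes (1 adjusted over the list alone, adjusted p = 0.422 with an estimated correlation). The monocyte score was 5.88 ± 0.16 in KO and 4.73 ± 0.39 in WT libraries (mean log2 CPM ± SD), the natural killer score 4.51 ± 0.13 and 2.94 ± 0.82 and the B cell score 5.48 ± 0.16 and 3.43 ± 1.52.

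In all, 248 genes were higher and 9 lower in CD4 KO than in CD4 WT controls (257 together of 12808 tested, 2324 at an unadjusted p under 0.05). DESeq2 called 789 and voom 1534, and none passed with the B cell score as a covariate. Without WT control 1 and 2 the count was 0 and 77, and without KO control 1, 2 and 3 it was 13, 6 and 0. No member of the effector, memory, heat shock, monocyte, natural killer and platelet lists passed without WT control 1 or without any 1 of the KO controls. Without WT control 2 the effector list had 1 member passing and the memory, heat shock, natural killer and platelet lists 0, and without WT control 3 the effector list had 12, the natural killer list 10, the monocyte list 5 and the platelet list 2. Of the B cell genes 24 passed without WT control 3 and 0 without any other single library. The antioxidant, interferon, Th1 and regulatory T cell genes numbered 0 without WT control 1, KO control 1 or KO control 3, and 0, 1, 1 and 2 without WT control 2. Without KO control 2 they were 0, 0, 0 and 1. The follicular helper genes were 0 without WT control 1 or KO control 3, and 2 without WT control 2, KO control 1 or KO control 2. Cdkn1a and Trbc1 passed only where WT control 3 was the library left out, and the ribosomal protein genes were 1 without WT control 2 and 0 without WT control 1 or any 1 of the KO controls. WT control 1 had the lowest monocyte, B cell and natural killer scores of the CD4 controls (4.36, 2.12 and 2.12).

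CD8 cells of the same untreated mice also differed in some effector and memory genes. Gzmm, a granule protease gene, was at 103.7 ± 17.3 in KO and 21.5 ± 6.65 in WT libraries (2.29 ± 0.26, adjusted p = 0.0043), and Tbx21 at 378 ± 31.1 and 129.6 ± 30.9 (1.57 ± 0.18, adjusted p = 0.00394). Of 29 effector and cytotoxic genes 5 rose and 15 did so adjusted over the list alone (median 1.12, adjusted p = 0.314 with an estimated correlation), with the death ligand gene Fasl at 1.65 ± 0.28 and Ctla2a at 1.52 ± 0.25. Of 19 memory genes 7 rose, and 16 were higher and 1 lower adjusted over the list alone (median 0.995, adjusted p = 0.314 with an estimated correlation). They included the interleukin receptor gene Il2rb (1.21 ± 0.18, 1284 ± 23.7 against 570.4 ± 22.2), the chemokine receptor gene Cxcr3 (1.54 ± 0.23) and Lgals1 (1.11 ± 0.17). Hspa8 (0.77 ± 0.11), Hsp90ab1 (0.77 ± 0.12), Stip1 (0.90 ± 0.17) and Ahsa1 (0.61 ± 0.12) rose of 17 heat shock genes (12 adjusted over the list alone, adjusted p = 0.314 with an estimated correlation). The CD8 WT lymphoma comparison uses the same WT controls, so its heat shock calls are not independent of these. The heat shock score was 5.77, 5.77 and 6.16 in the CD8 WT controls and 6.39 to 7.28 in the other CD8 libraries. Of 9 gamma-delta T cell genes the scavenger receptor genes Cd163l1 (2.55 ± 0.25) and 5830411N06Rik (2.24 ± 0.34) rose (3 adjusted over the list alone, adjusted p = 0.314 with an estimated correlation). Of 52 interferon genes Oas1a (1.59 ± 0.20) and Usp18 (1.29 ± 0.18) rose (7 adjusted over the list alone, adjusted p = 0.716 with an estimated correlation).

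Further named rises in CD8 KO controls were Dlg5 (2.59 ± 0.31, 19.5 ± 4.54 against 3.28 ± 0.735), the potassium channel gene Kcnk5 (2.20 ± 0.36), Dapk2 (2.05 ± 0.28), the E-cadherin gene Cdh1 (2.00 ± 0.37), the chondroitin sulfotransferase gene Chst11 (1.73 ± 0.20), Myl9 (1.68 ± 0.30) and H2-Q10 (1.64 ± 0.27). Rplp1 fell by 1.14 ± 0.19 (4231 ± 324 against 9520 ± 2819, adjusted p = 0.0223). Rgcc, a regulator of the cell cycle, fell by 1.83 ± 0.24 (11.5 ± 1.14 against 42.1 ± 5.59), and Ampd1 (-1.86 ± 0.35), the isoprenoid enzyme gene Idi1 (-1.76 ± 0.34), Tmie (-1.54 ± 0.22), Kif23 (-1.42 ± 0.25), Dph7 (-1.16 ± 0.23), H2-T23 (-1.16 ± 0.22), Matk (-1.13 ± 0.22) and Izumo1r (-1.10 ± 0.16) fell. None of 26 monocyte genes (median 0.91, adjusted p = 0.608 with an estimated correlation), 15 natural killer genes (median 1.05, adjusted p = 0.608) and 26 B cell genes (median 0.15, adjusted p = 0.79) passed over all genes tested or adjusted over the list alone. The natural killer score was 4.57 ± 0.11 in KO and 3.25 ± 1.44 in WT libraries and the monocyte score 5.49 ± 0.10 and 4.36 ± 1.18. No platelet gene passed over all genes tested, but the platelet score was higher in each KO control (3.40, 3.07 and 2.70) than in any WT control (1.54, 2.42 and 2.27). In CD8 KO control 1, 462 of 1103 olfactory receptor genes had a count, against 254 to 343 in the other libraries.

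In all, 51 genes were higher and 15 lower in CD8 KO than in CD8 WT controls (66 together of 12650 tested, 1861 at an unadjusted p under 0.05). DESeq2 called 375, voom 376 and edgeR with the Y-linked score as a covariate 14. Without WT control 1 and 3 the count was 39 and 18, and without KO control 1, 2 and 3 it was 17, 8 and 14. The effector genes that passed were 3 and 2 without WT control 1 and 3 and 2 without any 1 of the KO controls, and the memory genes 0 without WT control 1 or 3 or any 1 of the KO controls. The heat shock genes that passed were 2, 2 and 1 without WT control 1, 2 and 3 and 1, 0 and 0 without KO control 1, 2 and 3. The gamma-delta genes were 1 without WT control 1 or 3 and 1 without any 1 of the KO controls. Of the interferon genes 1 passed without KO control 2, and Idi1 and Kif23 did not pass without any 1 library.

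**Figure D2:**
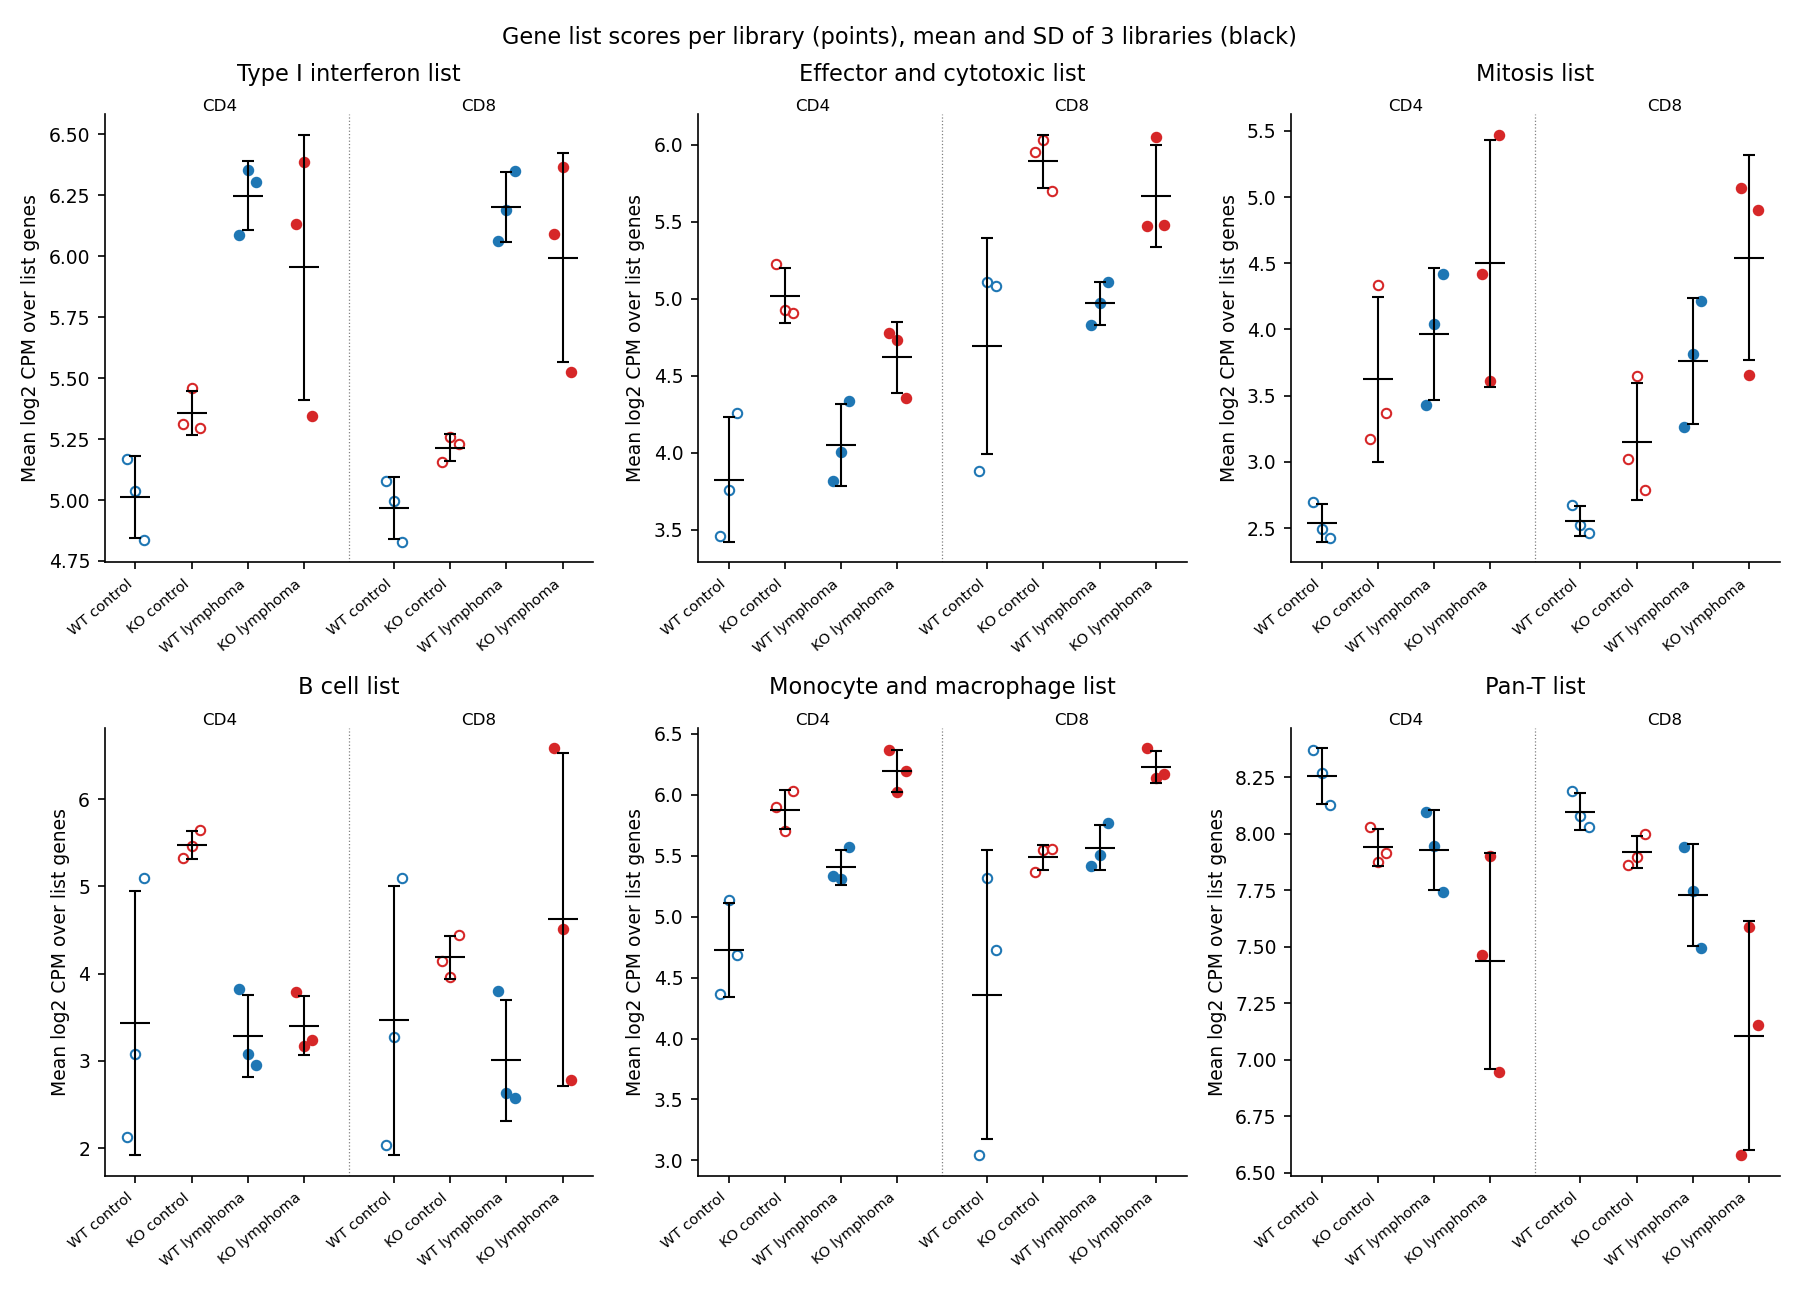
Mean log2 CPM of 6 gene lists in each library (points) by group, with the mean and SD of 3 libraries in black, open circles for control and filled circles for lymphoma, blue for WT and red for KO. The interferon score averaged 5.01 in CD4 WT control and 6.25 in CD4 WT lymphoma libraries, and the effector score 3.83 in CD4 WT and 5.02 in CD4 KO controls.

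The effect of genotype was also compared within mice that had lymphoma. In CD4 cells no gene passed by edgeR, with 1390 at an unadjusted p under 0.05, 85 called by DESeq2 and 46 by voom, and 1 gene passed without KO lymphoma 2. Tbx21 was at 98.3 ± 14.2 in KO and 57.9 ± 8.55 in WT libraries (0.76 ± 0.23, adjusted p = 0.359) and Maf at 413 ± 57.4 and 293 ± 20.7 (0.49 ± 0.14, adjusted p = 0.34). The transcription factor gene Ets1, on the naive and quiescent T cell list, differed by -0.56 ± 0.20 (adjusted p = 0.375). Of 20 genes on that list 10 were lower adjusted over the list alone (median -0.56, adjusted p = 0.512 with an estimated correlation). Of 19 memory genes 4 were higher adjusted over the list alone and of 29 effector genes none (medians 0.48 and 0.58, both with adjusted p = 0.512 with an estimated correlation). The macrophage gene C1qa was at 479 ± 31.1 and 243 ± 42.1 (0.98 ± 0.21, adjusted p = 0.242). Of 26 monocyte genes 14 and of 15 natural killer genes 4 were higher, and of 20 pan-T genes 8 were lower, adjusted over the list alone (each with adjusted p = 0.512 with an estimated correlation).

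In CD8 cells of mice with lymphoma, 9 genes were higher and 22 lower in KO than in WT libraries. Gzmm was at 76.0 ± 24.0 in KO and 19.6 ± 0.884 in WT libraries (1.95 ± 0.26, adjusted p = 0.0172), and Tbx21 at 260.2 ± 47.3 and 114 ± 4.03 (1.19 ± 0.18, adjusted p = 0.0249). These were the 2 of 29 effector genes that rose (7 adjusted over the list alone, median 0.79, adjusted p = 0.55 with an estimated correlation). Lef1, a transcription factor of naive T cells, was at 75.5 ± 27.1 and 184 ± 36.6 (-1.29 ± 0.23, adjusted p = 0.0486), the 1 of 20 naive and quiescent T cell genes that fell (13 adjusted over the list alone, median -0.53, adjusted p = 0.55 with an estimated correlation). The chemokine receptor gene Ccr9 (-2.17 ± 0.34), the p53 target Fas (-1.02 ± 0.15), the glycerol channel gene Aqp3 (-2.21 ± 0.39), Slc6a19 (-2.17 ± 0.31), Rgcc (-2.03 ± 0.25), Tmie (-1.98 ± 0.23), Pacsin1 (-1.51 ± 0.22), Gria3 (-1.44 ± 0.25), Rplp1 (-1.43 ± 0.19), H2-T23 (-1.28 ± 0.22) and Sept9 (-1.22 ± 0.20) fell. Dlg5 (2.54 ± 0.32), Samd3 (1.32 ± 0.22), Chst11 (1.08 ± 0.19), Chsy1 (0.73 ± 0.11), the neutrophil list gene G0s2 (1.15 ± 0.15), and Cd163l1 (2.95 ± 0.26) and 5830411N06Rik (2.43 ± 0.35) of 9 gamma-delta genes rose. The gamma-delta list had 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.55 with an estimated correlation).

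Other markers differed beside them in the CD8 lymphoma libraries. None of 17 erythroid genes passed over all genes tested, against 15 higher adjusted over the list alone (median 2.65, adjusted p = 0.55 with an estimated correlation), and of 17 neutrophil genes 10 were higher adjusted over the list alone (median 2.50, adjusted p = 0.55 with an estimated correlation). None of 26 B cell genes passed either way (median 2.46, adjusted p = 0.637), and of 20 pan-T genes 9 were lower adjusted over the list alone (median -0.55, adjusted p = 0.55 with an estimated correlation). The test had 2275 genes of 12650 at an unadjusted p under 0.05, DESeq2 called 531 and voom 19. The count of 31 was 5, 1 and 19 without WT lymphoma 1, 2 and 3 and 15, 978 and 3 without KO lymphoma 1, 2 and 3. No effector gene passed without any 1 of the WT lymphoma libraries or without KO lymphoma 3, and 3 did without KO lymphoma 2. Of the gamma-delta genes 1 passed without any 1 of the WT lymphoma libraries or without KO lymphoma 3. Of the naive and quiescent T cell genes 12 were lower without KO lymphoma 2 and 0 without any other single library, and of the p53 targets 5 and 0. The neutrophil genes were 2, 0 and 0 without KO lymphoma 2, KO lymphoma 3 and WT lymphoma 2.

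Genes that differed between genotypes in the same direction recurred. In at least 2 of the 4 KO against WT comparisons, 28 genes were called. Tbx21 and Chsy1 were higher and Rplp1 was lower in 3 of them. Rplp1 did not pass without any 1 of the KO controls in CD4 or CD8 cells, without CD4 WT control 1, or without WT lymphoma 1, WT lymphoma 2 or KO lymphoma 3 in CD8 cells. Tbx21 passed in CD8 controls under every omission, but in CD4 controls only without WT control 2 or 3 and in CD8 lymphoma mice only without KO lymphoma 1 or 2. Chsy1 passed in CD8 lymphoma mice only without KO lymphoma 2. Across genes, the genotype effects in control and lymphoma mice had a Pearson r of 0.48 in CD4 and 0.474 in CD8 cells (Spearman 0.555 and 0.539), and those of CD4 and CD8 cells 0.5 in control and 0.446 in lymphoma mice (Spearman 0.501 and 0.576), where both cell types came from the same mice. CD8 control and CD8 lymphoma mice shared 8 higher and 8 lower genes, where independent lists would share 0.04 and 0.03. CD4 and CD8 controls, from the same mice, shared 13 higher and 2 lower genes.

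Whether CD4 and CD8 cells responded to lymphoma to different degrees was tested directly. The main fit held no term for the mouse pool, although CD4 and CD8 libraries came from the same mice. In WT mice no gene passed by edgeR in that fit, with 180 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by voom. The interferon list had a median difference of -0.03 (CD8 minus CD4, none of 52 adjusted over the list alone, adjusted p = 0.987 with an estimated correlation), and of 17 regulatory T cell genes 5 were lower adjusted over the list alone (median -0.73, adjusted p = 0.108 with an estimated correlation). In KO mice no gene passed by edgeR without a block either, with 628 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by voom. With the mouse pool as a block edgeR called 25. Across genes, the WT responses of CD4 and CD8 cells had a Pearson r of 0.778 and a Spearman rho of 0.716. They shared 80 risers and 2 fallers, and 208 of the 209 CD4 genes tested in both had the same sign in CD8 cells. Both cell types came from the same mice, so differences between mice alone can make these responses alike. The KO responses of the 2 cell types had a Pearson r of 0.466 and a Spearman rho of 0.588.

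**Figure D3:**
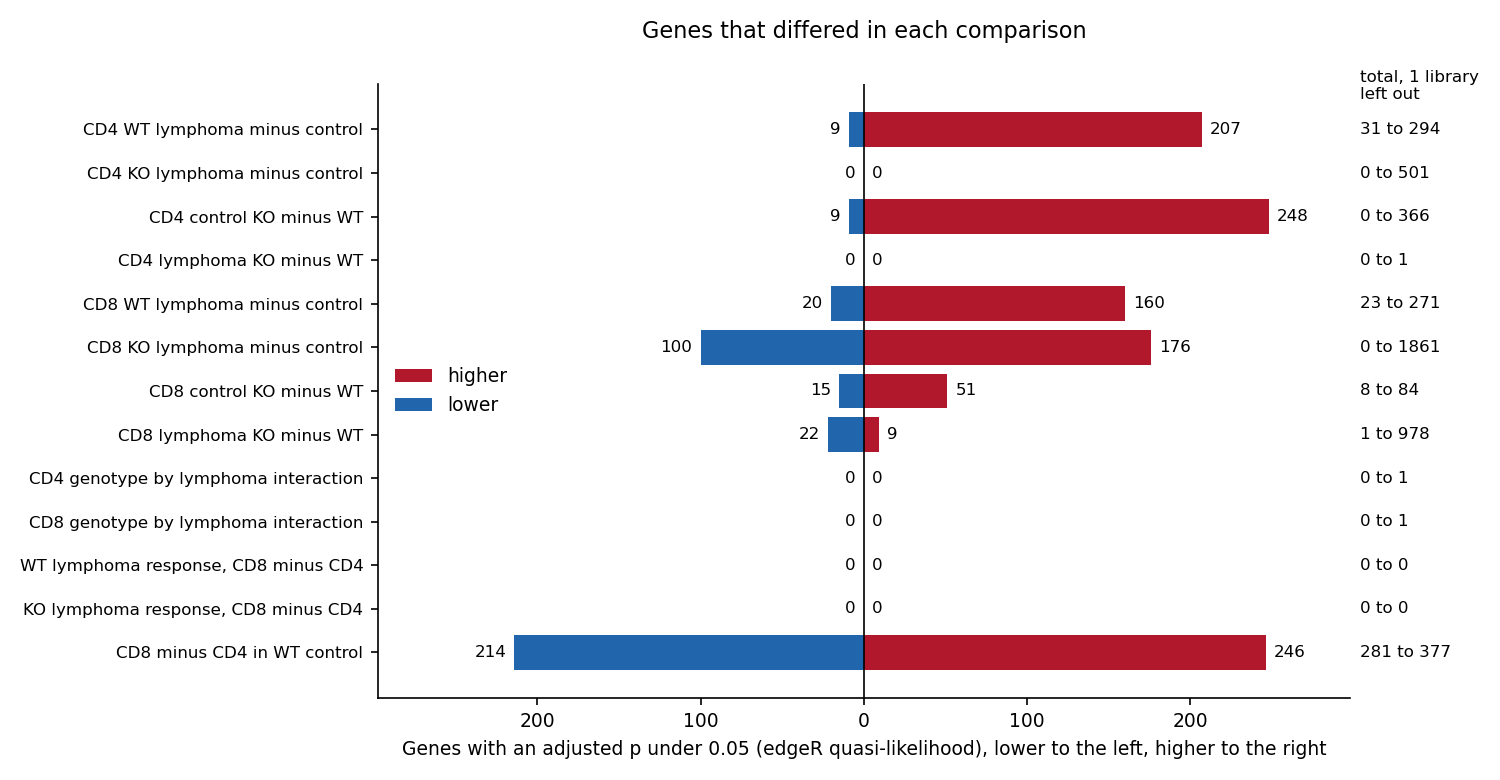
Number of genes with an adjusted p under 0.05 by edgeR in each of the 13 comparisons (horizontal axis, higher to the right in red and lower to the left in blue), with the range of the total when 1 library was left out at the right. The CD4 KO lymphoma comparison had 0 genes with every library and up to 501 with 1 left out.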

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

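Of the tests in this part, those on the sex mix of the pools and on B cells were written after the results were seen, and those on natural killer cells, monocytes and the position of Atm were planned. A test with the share of mice that carry a B identifier was replaced by the one on the sex mix.

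A set of results differed between CD4 and CD8 cells. In the response of KO mice to lymphoma, 25 of 26 B cell genes, 9 of 10 MHC class II genes and 13 of 18 erythroid genes differed between CD8 and CD4 cells adjusted over the list alone, none of them over all genes tested, each list with adjusted p = 0.447 with an estimated correlation. The rule of at least 50% of the members was chosen after the data were seen, and CD8 KO lymphoma 1 stood apart in these markers. Between KO and WT controls, the estimates for Itgae, Izumo1r and Matk had opposite signs in CD4 and CD8 cells, and each passed in 1 of the 2 cell types, Itgae in CD4 and the others in CD8 cells. The CD8 effect less the CD4 effect was -3.85 for Itgae, -1.55 for Izumo1r and -1.37 for Matk, and these differences were not tested. With groups of 3 no library was tested as an outlier.

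A part of the effector and memory genes was higher in untreated KO than WT cells (7 of 29 and 8 of 19 in CD4, 5 of 29 and 7 of 19 in CD8 cells), while the lists did not pass with an estimated correlation (adjusted p = 0.0997 and 0.129 in CD4, 0.314 for both in CD8 cells). Both CD4 counts were 0 without WT control 1 or any 1 of the KO controls. In CD8 cells, with 1 library left out, the effector count went down to 2 and the memory count to 0. Natural killer cells in the libraries could add to the rise of these genes, since with their score as a covariate the 15 called members kept a median 59.4% of the log2 fold change in CD4 cells (quartiles 47.4 to 74.3) with none still called, and 11 members kept 79.6% in CD8 cells with 1 called. The CD4 result may thus in part come from other cells or from T cells that share natural killer genes, and these cannot be told apart here. Of 26 monocyte and macrophage genes 14 rose in the same CD4 comparison, and their score was not tested as a covariate for the effector and memory genes. The sex mix of the pools differed between the groups (Y-linked RNA of 68.1, 189 and 125 CPM in CD4 WT and 2.69, 1.25 and 57.7 in CD4 KO controls). With the Y-linked score as a covariate 111% was kept in CD4 (10 called) and 103% in CD8 cells (2 called). The median log2 fold change went from 1.4 to 1.26 in CD4 and from 1.2 to 1.3 in CD8 cells. Standard errors grew from 0.26 to 0.32 and from 0.2 to 0.23. Of the variance of this score, 43.6% lay between the groups in CD4 and 38.6% in CD8 libraries. The score thus did not remove the fold changes, but the sex mix is not excluded as a part of the cause. With the B cell score 99.2% was kept in CD8 cells (6 called), so B cells are unlikely as the whole cause there. In CD4 cells 90.4% was kept with 0 called. The median log2 fold change went from 1.4 to 1.14 and the standard error from 0.26 to 0.37. As 65.2% of the variance of the score lay between the groups of CD4 libraries, B cells are not excluded there. The replaced test on the B identifier kept 98.5% in CD4 and 102% in CD8 cells, and the sex mix score that held Kdm5d kept 111 and 102%.

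Of 52 interferon-stimulated genes, 28 were higher with lymphoma in CD4 WT, 29 in CD8 WT and 22 in CD8 KO cells, and none passed in CD4 KO cells, where KO lymphoma 1 and 2 had interferon scores of 6.13 and 6.39 (WT lymphoma 6.09 to 6.35) and KO lymphoma 3 had 5.34. The list did not pass with an estimated correlation in any of these (adjusted p = 0.262, 0.299, 0.461 and 0.458). With 1 library left out the counts of 28, 29 and 22 went down to as few as 16, 13 and 0. Interferon made in tumor-bearing mice could be a biological cause of the calls, which was not tested. The score of monocytes and macrophages was also used as a covariate. The median fold kept was 115% in CD4 WT, 102% in CD8 WT and 100% in CD8 KO cells. The calls went from 28 to 0, 29 to 6 and 22 to 4, with standard errors that grew from 0.26 to 0.41, from 0.23 to 0.32 and from 0.26 to 0.30. Of the variance of this score, 89% lay between the groups in CD4 and 65% in CD8 libraries. The test thus separates the score poorly from lymphoma, and monocytes and macrophages as a cause are not excluded. B cells in the libraries are unlikely as the whole cause, with 99.5, 99.8 and 98.6% kept and 28, 27 and 18 genes still called. In both WT comparisons the median fold change of the B cell genes was negative, so the kept share adds little there.

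Of the 28 genes that recurred between genotypes, Hspa8 and Rplp1 lie within 20 Mb of Atm, which is 7.14% (exact 95% limits 0.877 to 23.5). Endod1, Prkar2a and Tmie also lie on chromosome 9, outside that window (starting at 14353990, 108689314 and 110865711), and the whole chromosome was not tested. The remaining genes lie on other chromosomes. Donor strain DNA that acts on genes within this window is therefore unlikely as the cause for most of the set. Effects of such DNA on genes outside the window, or of a longer stretch of it, were not tested. For a part of the set, donor strain DNA and the loss of Atm cannot be told apart, with 280 of 12669 other tested genes in the window (odds ratio 3.4, exact Fisher p = 0.128).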

How the results depend on the processing

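The Y-linked and pan-T covariates were chosen after the data were seen, as were the list tests with the Y-linked score and with each library left out, and the other alternatives were planned. No gene named for passing reversed in direction under any alternative. Such genes were picked because they passed, and the largest rises and falls also for no overlap between libraries. A reversal was thus unlikely from the start. DESeq2 size factors in edgeR and the removal of genes of other cell types moved no count by more than 1.5 times, and no scaling moved the median log2 fold change by more than 0.1. None of the 244 list calls made with the preset correlation in the other 12 comparisons held with an estimated one. In CD8 against CD4 WT controls the lineage, regulatory T cell and follicular helper lists passed with an estimated correlation, and the lists there were not rerun under the other alternatives. The cause of the moves below was not tested.

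With DESeq2, which on simulated data called 19 to 38 unchanged genes among 160 to 183, the counts of called genes were 678 (edgeR 216) in CD4 WT lymphoma, 343 (0) in CD4 KO lymphoma, 789 (257) in CD4 control KO against WT, 85 (0) in CD4 lymphoma KO against WT, 799 (180) in CD8 WT lymphoma, 1499 (276) in CD8 KO lymphoma, 375 (66) in CD8 control KO against WT and 531 (31) in CD8 lymphoma KO against WT. It called 1 gene in each interaction, 1 in the WT and 4 in the KO difference between CD8 and CD4 responses. With voom the counts were 703 in CD4 KO lymphoma, 1534 in CD4 control KO against WT, 46 in CD4 lymphoma KO against WT, 901 in CD8 WT lymphoma, 481 in CD8 KO lymphoma, 376 in CD8 control KO against WT and 19 in CD8 lymphoma KO against WT.

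With the Y-linked score as a covariate the counts were 435 in CD4 WT lymphoma, 3 in CD4 KO lymphoma, 395 in CD4 control KO against WT, 112 in CD8 WT lymphoma and 14 in CD8 control KO against WT. The pan-T score gave 8 in CD4 KO lymphoma, 144 in CD4 control KO against WT, 1 in CD4 lymphoma KO against WT, 65 in CD8 WT lymphoma, 0 in CD8 KO lymphoma and 7 in CD8 lymphoma KO against WT. The B identifier share gave 79 in CD4 and 42 in CD8 control KO against WT, 443 in CD8 KO lymphoma and 18 in CD8 lymphoma KO against WT. The B cell score gave 0 in CD4 control KO against WT and 11 in CD8 lymphoma KO against WT.

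With only the 6 libraries compared the counts were 380 in CD4 WT lymphoma, 17 in CD4 KO lymphoma, 925 in CD4 control KO against WT, 1 in CD4 lymphoma KO against WT, 595 in CD8 WT lymphoma, 130 in CD8 control KO against WT and 1 in CD8 lymphoma KO against WT. All 24 libraries in 1 fit gave 20 in CD4 KO lymphoma, 1 in CD4 lymphoma KO against WT, 376 in CD8 WT lymphoma and 629 in CD8 KO lymphoma. No filter gave 27 in CD4 KO lymphoma, 3 in CD4 lymphoma KO against WT and 62 in CD8 lymphoma KO against WT, and the stricter filter 416 in CD8 KO lymphoma and 63 in CD8 lymphoma KO against WT. Upper-quartile normalization gave 65 in CD8 lymphoma KO against WT. The replicate number as a block gave 25 in CD8 KO lymphoma and 17 in CD8 lymphoma KO against WT, and the mouse pool as a block 25 in the KO difference between CD8 and CD4 responses.

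With 1 library left out the counts ran from 31 to 294 in CD4 WT lymphoma, 0 to 501 in CD4 KO lymphoma, 0 to 366 in CD4 control KO against WT, 0 to 1 in CD4 lymphoma KO against WT, 23 to 271 in CD8 WT lymphoma, 0 to 1861 in CD8 KO lymphoma, 8 to 84 in CD8 control KO against WT, 1 to 978 in CD8 lymphoma KO against WT and 281 to 377 in CD8 against CD4 WT controls. Both interactions ran from 0 to 1.

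For the lists whose direction in the camera test turned, the median log2 fold change under that alternative is given, with the other end of the range with 1 library left out in parentheses. Without CD4 KO lymphoma 3 the oxidative phosphorylation list was at -0.0121 (0.2103) in CD4 KO lymphoma, -0.0254 (0.1855) in CD4 lymphoma KO against WT and -0.0664 (0.1962) in the CD4 interaction, the S phase list at -0.1275 (0.7592) in CD4 lymphoma KO against WT and the naive list at 0.0237 (-0.4449) in the CD4 interaction. With the Y-linked score the CD4 interaction had the naive list at 0.0392 and oxidative phosphorylation at -0.0742, and CD8 control KO against WT had the sex-linked list at 0.1832. The mitochondrially encoded list was at 0.0804 (-0.5622) in CD4 control KO against WT without WT control 2, and the interferon list at -0.0044 (-0.3685) in CD8 lymphoma KO against WT without KO lymphoma 3. In the CD8 interaction the monocyte list was at 0.07 (-0.7109) without WT control 1 and the erythroid list at 0.2409 (2.2861) without KO lymphoma 1. In the WT difference between CD8 and CD4 responses the monocyte list was at -0.0387 (0.9039) without CD8 WT control 1. At 6470482 to 10196062 counts per library, genes of low expression were filtered out, and 3′ tags do not resolve isoforms.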

Other observations

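The exchange of group labels in this part was planned for every comparison. CD8 KO control 1 held tags from many genes that the other libraries lacked, with 756 genes counted in it alone (41 to 90 in the others) and 17707 genes detected, the most of any library. Kdm5d was at 66 CPM in it and at most 32.9 elsewhere. CD4 KO control 2 had 3.62% of its counts on erythroid list genes.

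Labels were exchanged between the groups of each comparison in every split of 3 against 3. With 10 splits, too few for a share under 0.05, the real grouping called the most genes in 7 of these comparisons, 1 split of 10 in each. Real and highest other counts were 216 and 0 for CD4 WT lymphoma, 257 and 0 for CD4 control KO against WT, 180 and 0 for CD8 WT lymphoma, 276 and 1 for CD8 KO lymphoma, 66 and 1 for CD8 control KO against WT, 31 and 0 for CD8 lymphoma KO against WT, and 460 and 4 for CD8 against CD4 WT controls. In CD4 KO lymphoma all 10 splits called at least the real count of 0, with a highest of 8, and in the differences between CD8 and CD4 responses all 10 splits called 0. In CD4 lymphoma KO against WT the real count was 0 and the highest other 51, with WT lymphoma 1 and KO lymphoma 2 exchanged. That split puts libraries of the same number on the same side, and the same-number libraries of this comparison had residual correlations of 0.436, 0.305 and 0.425, a structure of the samples that the count of 0 does not take into account. Over the 4 splits that part all same-number libraries, the real one included, the highest other count was 0. In the CD4 interaction the real count was 0 and the highest of 100 splits 28, in a split with the same exchange of lymphoma libraries, and in the CD8 interaction 0 and 1, with all 100 splits at least as large as the real count.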
